A study of Mus musculus with 2 samples.

How the data were processed

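The series holds 2 libraries of ribosomal RNA-depleted total RNA from the nucleoplasmic fraction of mouse bone marrow-derived macrophages treated with lipid A. Lipid A is the membrane anchor of bacterial lipopolysaccharide and activates the receptor TLR4. Per the labels, both libraries come from cells of strain C57BL/6J given 100 ng/ml for 50 minutes, and they are separate biological replicates of 1 group. The description names the nucleoplasm, whereas the source and cell part labels say nucleus. Per the labels, the RNA input was 500 ng for replicate 1 and 1 µg for replicate 2, and fragments were in the range 250 to 400, with no unit given. No untreated library was analysed here, so no value can be read as a response to lipid A, and all comparisons are between gene lists inside these libraries, between the replicates or between the quantifications.

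The deposited gene tables and transcript tables hold expected counts and TPM (transcripts per 1000000) in the column layout of RSEM, per the file headers. A further deposited transcript table per library holds estimated counts and TPM in the column layout of kallisto, per the file headers. The authors' readme files name the mm10 genome and annotation M21, and say that the tables in the first layout were made from alignments to transcripts and those in the other from the reads. Program names and versions, trimming, strand settings and filters are not given in the sources used here. TPM divides counts by an effective transcript length, so a few counts on an RNA shorter than the fragments can become a very large TPM, and every other TPM falls in proportion. Reads from near-identical copies, from overlapping genes and, as the strand setting is not given, from antisense partners cannot be separated with certainty.

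Gene symbols, coordinates and classes came from the GENCODE M21 annotation of the same build, in which all 55536 gene identifiers of the tables were found. Each gene table also holds 97 spike-in rows and 26248 rows with numeric identifiers only, which name no gene and were left out of CPM (counts per 1000000 counts of gene rows) and of tests. The spike-in rows held 0.504% of expected counts in replicate 1 and 0.0967% in replicate 2, and the numeric rows held 0.000106% and 0.000102%. Of the 2 list symbols that carry 2 gene identifiers, Rmrp and Ddit3, the values were summed per symbol. With all rows the tables held 10395300 expected counts in replicate 1 and 20515408 in replicate 2, of which 10342882 and 20495545 lay in gene rows, and the other quantification 19734726 and 28995544 estimated counts. A count of 0 allows up to 0.290 CPM in replicate 1 and 0.146 in replicate 2, taking 3 counts as the limit. Such limits and the intervals of shares of counts cover counting error only, since reads without molecular identifiers are not independent molecules. The intervals of a share or a median of genes cover the sampling of genes only.

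Before the data were examined, 24 gene lists were fixed with 8 list pairs to compare. The level of a gene was log2(TPM + 1), averaged over the libraries, and so understates differences among genes of low TPM. List medians were compared with a two-sided permutation test over genes with 100000 resamples, with Benjamini-Hochberg adjustment over the 8 pairs. The smallest p that it can give is 2e-05. Genes are not independent replicates, so these p-values describe the lists in these libraries and not a wider population of cultures. Each list's median was also set among 10000 random lists of the same size drawn from protein-coding genes. The noncoding isoform share was the percent of a protein-coding gene's transcript TPM in isoforms not annotated as protein-coding, for genes with a mean TPM of at least 1 and at least 1 such isoform. A nuclear fraction can hold incompletely spliced RNA, which a transcript quantification can assign to such isoforms.

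The replicates were compared in 4 ways. Expected counts were rounded to whole numbers, and the biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 with an intercept only, TMM scaling and genes with at least 10 counts in both libraries. The share of genes within 2-fold was taken among genes with a mean TPM of at least 1 after division by the median ratio. The median log2 ratio of each list was set among 10000 random lists of the same size matched on mean TPM in 20 bins, and a list outside the 2.5th to 97.5th percentile was taken to stand apart. A chi-square statistic over genes checked whether the libraries could be copies of each other. Values are given as mean ± SD over the 2 libraries.

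The genes named were chosen by a rule fixed before the data were examined. It took the 4 highest and 3 lowest genes of each list, and other members where a list is counted. It also took the 15 highest genes of at least 200 nt and the 5 highest shorter ones, and the 6 largest ratios between the replicates in each direction among genes with at least 100 counts in a library, on the log2(TPM + 1) scale. Last came the 8 list genes with a mean TPM of at least 5 and the highest noncoding isoform share, and the 6 response genes that differed most between the quantifications. Some genes that this rule takes are not reported here.

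Alternatives to each choice covered the pseudocount (0.1 and 0.01), filters on low values, CPM, TPM rescaled over nuclear protein-coding genes, the other quantification, means for medians, DESeq2 1.42.0 size factors and dispersions, and leaving out each replicate. The steps were tested on simulated data. In 200 runs with 18 genes per list, the permutation test called 3% of unshifted pairs and 99.5% of pairs shifted by 3 on the log2 scale. In 50 runs over 12943 genes, the list comparison between replicates called 8% of unshifted lists and 100% of lists shifted by 1. For the replicate spread over 12774 simulated genes, a value set to 0.2 came back as 0.198, and as 0.234 when 200 genes were changed 4-fold. Calculations used Python 3.11 with numpy, scipy 1.17.1 and pandas, and R 4.3.3.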

Results

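The data describe RNA in the nucleoplasm of bone marrow-derived macrophages, which are macrophages grown from mouse marrow, 50 minutes after addition of 100 ng/ml lipid A. The 1 group had 2 biological replicates, with 10395300 expected counts in replicate 1 and 20515408 in replicate 2. Positions of genes are on the mm10 build. At 1 TPM or more, replicate 1 held 11976 genes, 9453 of them protein-coding, and replicate 2 held 10756 genes, 8685 of them protein-coding. The median gene with a mean TPM of at least 1 had a log2 TPM ratio of -0.69 (replicate 2 over replicate 1), so the SDs of single genes below include this common shift. The numbers of genes at 1 TPM or more include it too, so they do not show that replicate 2 detected fewer genes.

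The first comparison asked which classes of lipid A response genes were abundant in the nucleoplasm at this time. NF-kB-driven cytokine genes had the highest median TPM of the response lists, 294 ± 131 TPM (SD, n = 2), and all 18 were at 1 TPM or more in both libraries. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, minus strand), the gene of tumour necrosis factor, was at 1300 ± 329 TPM (SD, n = 2). The neutrophil-attracting chemokine gene Cxcl2 followed at 877 ± 288 TPM, then Il1b at 701 ± 207 TPM and Tnfsf9 at 587 ± 119 TPM (SD, n = 2). The lowest members were Il23a at 12.3 ± 8.02 TPM, Lif at 7.16 ± 0.827 TPM and Cxcl3 at 2.59 ± 0.806 TPM (SD, n = 2).

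Genes of the NF-kB feedback list, which hold inhibitors and subunits of the pathway and some of its early surface targets, had a median of 114 ± 27.5 TPM (SD, n = 2), and all 18 were at 10 TPM or more in both libraries. Tnfaip3 (ENSMUSG00000019850.11, chromosome 10, 19000910 to 19015657, minus strand), which encodes the deubiquitinase A20, led at 756 ± 310 TPM (SD, n = 2). The inhibitor gene Nfkbia was at 540.5 ± 45.8 TPM, the adhesion molecule gene Icam1 at 454 ± 67.1 TPM and Nfkbiz at 374 ± 161 TPM (SD, n = 2). Nfkbib at 59.9 ± 20.0 TPM, Relb at 48.3 ± 3.29 TPM and Bcl3 at 21.7 ± 7.84 TPM were the lowest (SD, n = 2). All 20 immediate early genes were at 1 TPM or more in both libraries, with a median of 55.5 ± 9.31 TPM (SD, n = 2). The phosphatase gene Dusp1 (ENSMUSG00000024190.7, chromosome 17, 26505590 to 26562128, minus strand) was at 371 ± 106 TPM, Klf6 at 275 ± 116 TPM, Junb at 186 ± 10.5 TPM and Atf3 at 175 ± 34.3 TPM (SD, n = 2). The transcription factor genes Fos and Egr1 were lower at 53.9 ± 22.9 TPM and 51.9 ± 21.1 TPM (SD, n = 2). Myc at 11.3 ± 2.55 TPM, Fosb at 11.2 ± 8.37 TPM and Egr3 at 6.32 ± 1.23 TPM closed the list (SD, n = 2).

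The secondary response list, genes known to need new protein synthesis or chromatin remodelling in many settings, had a median of 2.24 ± 0.810 TPM (SD, n = 2), and 10 of its 18 genes were at 1 TPM or more in both libraries. Of the others, 7 were below 1 TPM in both. Acod1, which encodes the itaconate-producing enzyme, reached 226 ± 58.8 TPM and the chemokine gene Ccl5 174 ± 17.4 TPM, with Mmp13 at 32.1 ± 8.54 TPM, Ebi3 at 31.5 ± 2.06 TPM and Il12b at 30.4 ± 6.39 TPM (SD, n = 2). Il6 was at 3.04 ± 1.46 TPM and the nitric oxide synthase gene Nos2 at 0.310 ± 0.184 TPM (SD, n = 2). Fpr1 rested on 1 count in replicate 1 and 3 in replicate 2, Il12a on 0 and 3, and Il33 had 0 counts in both. The interferon response list had a median of 35.2 ± 13.7 TPM (SD, n = 2), and all 25 genes were at 1 TPM or more in both libraries. The antiviral genes Rsad2 (ENSMUSG00000020641.16, chromosome 12, 26442746 to 26456452, minus strand) and Ifih1 were at 384 ± 197 TPM and 279 ± 130 TPM, Gbp5 was at 232 ± 80.9 TPM and Oasl2 at 179 ± 82.1 TPM (SD, n = 2). Usp18 at 5.48 ± 0.566 TPM, Ifi44 at 4.25 ± 0.70 TPM and Igtp at 3.44 ± 0.361 TPM were the lowest (SD, n = 2).

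On the log2(TPM + 1) scale the median of the cytokine list lay 6.48 above that of the secondary response list, with 6.70 in replicate 1 and 6.25 in replicate 2 (two-sided permutation test over genes, adjusted p = 5.3e-05, Benjamini-Hochberg over 8 pairs). The feedback list lay 5.16 above the secondary list, with 5.22 and 5.17 in the libraries (permutation test, adjusted p = 0.00012). The immediate early list lay 4.14 above it, with 4.13 and 4.23 (permutation test, adjusted p = 0.00016), and the interferon list 3.55 above it, with 3.67 and 3.32 (permutation test, adjusted p = 5.3e-05). With only genes of a mean TPM of at least 1, a filter that removes secondary response genes such as Nos2 and Il12a, these last differences were 1.93 (permutation test, adjusted p = 0.05, at the threshold) and 1.34 (adjusted p = 0.068), and both tests no longer passed. Over all alternatives the adjusted p ranged from 8e-05 to 0.05 for the immediate early list and from 5.3e-05 to 0.068 for the interferon list. The difference to the secondary list fell to 4.27 at the lowest for cytokines and to 2.96 for feedback genes. Their adjusted p in the same permutation test was at most 0.028 and 0.0056. Against the interferon list, the cytokine list was higher by 2.93 (permutation test, adjusted p = 0.00061) and the feedback list by 1.61 (permutation test, adjusted p = 0.0068). The order of the cytokine and feedback lists, a pair that was not tested, turned on the CPM scale, where these differences were 1.91 and 2.18. The immediate early list was 0.59 above the interferon list, with 0.46 in replicate 1 and 0.91 in replicate 2, and did not pass the permutation test (adjusted p = 0.068). Without replicate 1 that difference of 0.91 had an adjusted p of 0.013 in the same permutation test, within a range of 0.013 to 0.18 over the alternatives.

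**Figure D1:**
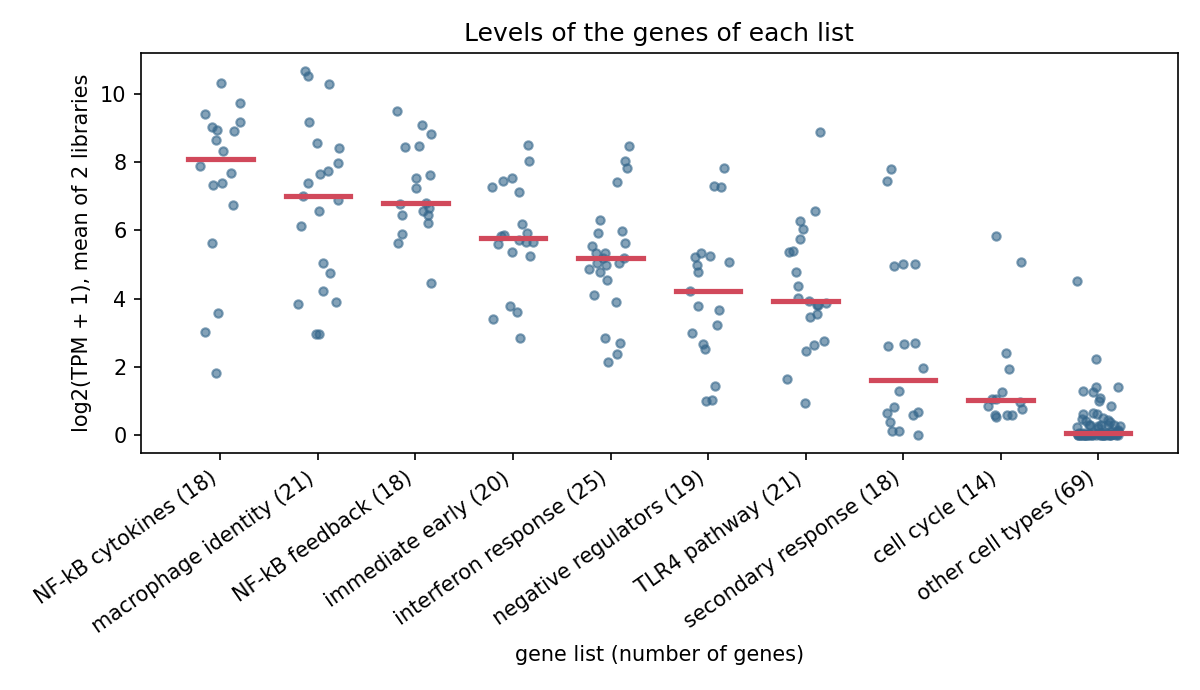
Each point is a gene of a list, at its log2(TPM + 1) averaged over the 2 libraries, with the list median as a red bar and the number of genes in brackets. Of the response lists the cytokine list has the highest median on this scale, 8.10 (not on the CPM scale), the secondary response list lies at 1.63 with Acod1 and Ccl5 far above its other members, and the pooled markers of other cell types lie near 0.

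Negative regulators and TLR4 pathway genes had medians of 19.2 ± 10.3 TPM and 14.6 ± 5.37 TPM (SD, n = 2). These lay between the medians of the interferon and secondary response lists, in pairs that were not tested. Of 19 negative regulators, 18 were at 1 TPM or more in both libraries. The mRNA-decay factor gene Zfp36 was at 227 ± 45.5 TPM, the interleukin-1 receptor antagonist gene Il1rn at 163 ± 71.1 TPM, Socs3 at 152 ± 5.65 TPM and Trib1 at 40.6 ± 11.3 TPM (SD, n = 2). Pdcd4 at 1.74 ± 0.410 TPM, Nr4a2 at 1.08 ± 0.863 TPM and Socs1 at 1.05 ± 0.0707 TPM were the lowest (SD, n = 2). Of 21 genes of the TLR4 pathway, 20 were at 1 TPM or more in both libraries. The co-receptor gene Cd14 stood out at 483 ± 130 TPM, with Irak2 at 96.0 ± 29.3 TPM, Tbk1 at 80.5 ± 34.2 TPM and Irf3 at 65.4 ± 14.6 TPM (SD, n = 2). Irak4 at 4.58 ± 1.24 TPM, Tab1 at 2.30 ± 1.48 TPM and Tirap at 0.935 ± 0.134 TPM were the lowest (SD, n = 2). Among 10000 random lists of protein-coding genes of the same size, the medians of the cytokine, feedback, immediate early, interferon, negative regulator and TLR4 pathway lists were each at percentile 100, as were those of the macrophage identity, housekeeping, ribosomal protein and heat shock lists, and that of the secondary list was at percentile 92.4. The random lists include genes that are not expressed, and those of the secondary list's size had a median level of 0.40. Percentile 100 therefore does not set the response lists apart from other expressed genes.

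The second comparison asked whether the RNA carried the identity of macrophages. All 21 macrophage identity genes were at 1 TPM or more in both libraries, with a median of 129 ± 6.99 TPM (SD, n = 2). The lysosomal protease genes Ctsb and Ctsd were at 1643 ± 332 TPM and 1248 ± 101 TPM, the lysozyme gene Lyz2 at 1484 ± 32.4 TPM and the pore-forming protein gene Mpeg1 at 593 ± 148 TPM (SD, n = 2). Aif1 at 7.12 ± 2.87 TPM and the transcription factor gene Cebpa at 6.89 ± 1.23 TPM were the lowest (SD, n = 2). Of 69 markers of other cell types, 6 were at 1 TPM or more in both libraries and 23 had 0 counts in both. The identity list lay 6.96 above these markers on the log2 scale, with 7.04 in replicate 1 and 6.93 in replicate 2 (permutation test, adjusted p = 5.3e-05). The size of this difference depends on the scale and ranged from 5.66 to 11.9 over the alternatives. On TPM rescaled over nuclear protein-coding genes, 15 of the 69 were at 1 TPM or more, and in the other quantification 2 were.

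The other-cell markers were low list by list. In the T and NK cell list Cd4 was at 22.1 ± 5.49 TPM (SD, n = 2), 6 of 11 genes had 0 counts in both libraries, and Cd2, Lck, Cd3d and Gata3 had at most 6 counts in either. The B cell list reached 1.42 ± 0.0424 TPM with Cd22 (SD, n = 2), and 9 of its 10 genes were below 1 TPM in both libraries. Of 11 neutrophil markers, Ltf was at 1.67 ± 0.156 TPM and S100a8 at 1.47 ± 0.283 TPM (SD, n = 2), on at most 27 counts. Of 10 erythroid markers 9 were below 1 TPM in both libraries, with Alas2 highest at 0.815 ± 0.304 TPM (SD, n = 2). Batf3 led the 7 dendritic cell markers at 1.69 ± 0.495 TPM, Kit the 9 mast cell and basophil markers at 1.17 ± 0.523 TPM and the endothelial receptor gene Kdr the 11 stromal markers at 3.66 ± 0.332 TPM (SD, n = 2). In the alternative activation list Tgm2 was at 92.8 ± 26.8 TPM and Clec10a at 14.8 ± 0.106 TPM, whereas Arg1 was at 0.10 ± 0.141 TPM (SD, n = 2), on 0 and 3 counts.

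The noncoding transcript Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254, minus strand), which coats the inactive X chromosome of female cells, was at 306 ± 83.2 TPM (SD, n = 2). The 4 Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 counts in both libraries, which allows each up to 0.290 CPM in replicate 1 and 0.146 in replicate 2. Of 14 cell cycle genes 5 were at 1 TPM or more in both libraries. Mki67 was at 57.9 ± 22.8 TPM and Pcna at 33.6 ± 11.5 TPM, but Top2a was at 4.46 ± 1.77 TPM, Aurkb at 0.495 ± 0.134 TPM and Plk1 at 0.445 ± 0.134 TPM (SD, n = 2). In the heat shock and stress list Gadd45b was at 271 ± 23.1 TPM and the chaperone gene Hspa5 at 200 ± 16.5 TPM, whereas Hspa1a was at 2.19 ± 0.332 TPM and Dnajb1 at 1.17 ± 0.410 TPM (SD, n = 2). All 15 housekeeping genes were at 1 TPM or more in both libraries, with the actin gene Actb highest at 532 ± 222 TPM (SD, n = 2).

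The third comparison described the make-up of the nucleoplasmic RNA. Small RNA genes took 64.7 ± 12.4% of TPM (SD, n = 2), nuclear protein-coding genes 21.6 ± 6.48%, long noncoding genes 6.07 ± 0.0543% and the mitochondrial genome 5.05 ± 3.82% (SD, n = 2), with 7.75% in replicate 1 and 2.34% in replicate 2. Mitochondria-derived pseudogenes were counted among pseudogenes and other genes, which took 3.97% of TPM in replicate 1 and 1.14% in replicate 2. The mitochondrial share may therefore be understated. The small SD of the long noncoding class covers opposite shifts of its members. A Rmrp entry annotated as long noncoding held 0.357% of TPM in replicate 1 and 3.56% in replicate 2, and Malat1 held 3.26% and 1.01%. By share of expected counts, which carries no length correction, the order was another one, with 69.6 ± 2.54% for nuclear protein-coding genes, 16.4 ± 1.32% for long noncoding genes, 8.05 ± 6.27% for small RNA genes and 4.41 ± 1.78% for the mitochondrial genome (SD, n = 2). The 7SK RNA gene Rn7sk (ENSMUSG00000065037.1, chromosome 9, 78175303 to 78175633, minus strand), whose RNA holds the elongation factor P-TEFb in reserve, led all genes at 206291 ± 63750 TPM (SD, n = 2). The RNase MRP and RNase P RNA genes Rmrp and Rpph1 were at 82967 ± 29904 TPM and 54210 ± 28716 TPM, and the signal recognition particle RNA copies Rn7s2 and Rn7s1 at 49776 ± 33773 TPM and 46485 ± 36970 TPM (SD, n = 2). Rmrp is annotated under 2 overlapping genes and Rn7s1 and Rn7s2 are near-identical copies, so the division of reads within each pair is uncertain. The 5 highest genes under 200 nt were the small nuclear RNA copies Gm22513, Gm25939, Gm23472 and Gm23444 and the snoRNA gene Gm22988, on 510 to 8298 counts each. Gm23472 and Gm23444 had the same value, 11202 ± 3874 TPM (SD, n = 2), and Gm24497, a further copy, shared it in replicate 1 only.

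**Figure D2:**
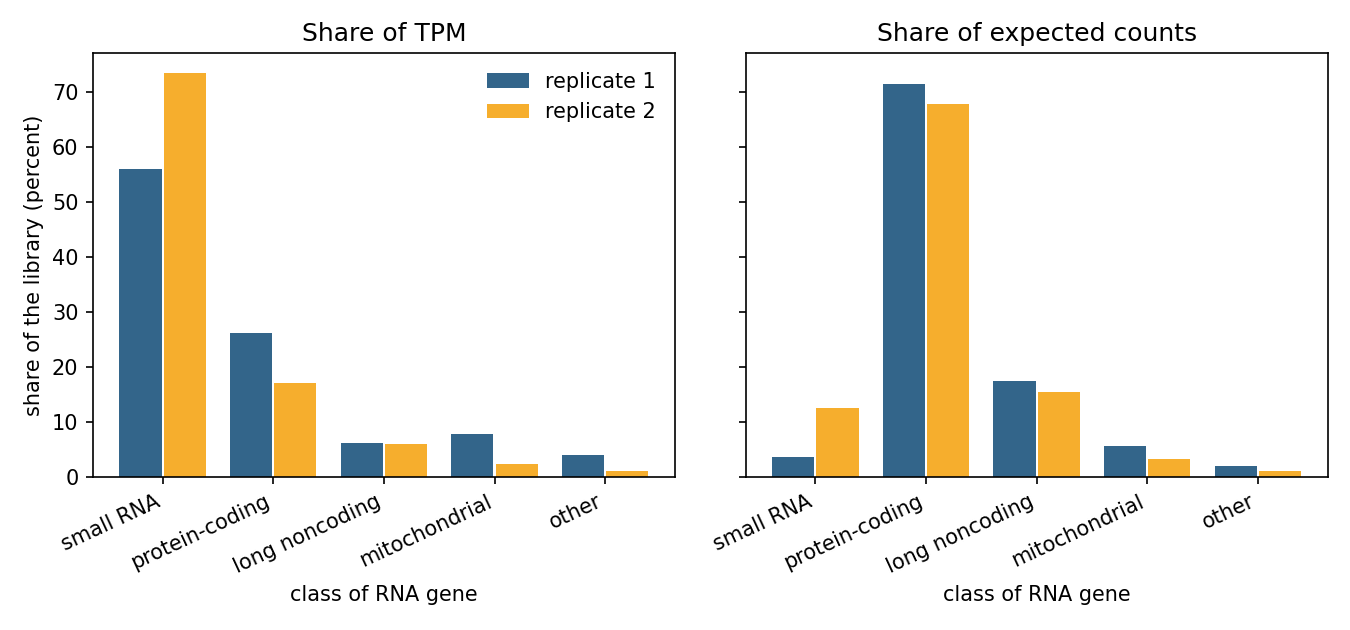
Bars give the share of each class of RNA gene in each library, in percent of TPM on the left and of expected counts on the right. Small RNA genes hold 56.0% and 73.4% of TPM in replicates 1 and 2 but 3.61% and 12.5% of expected counts, and nuclear protein-coding genes hold 71.4% and 67.8% of expected counts.

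Among long noncoding RNAs, Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672, minus strand), a nuclear speckle RNA, held 11.1% of expected counts in replicate 1 and 9.04% in replicate 2, at 32582 and 10080 TPM. The paraspeckle RNA Neat1 was at 1245 ± 320 TPM, the miR-155 host gene Mir155hg at 293 ± 91.6 TPM and Firre at 61.1 ± 20.6 TPM (SD, n = 2). Of 13 nuclear noncoding RNA genes 9 were at 1 TPM or more in both libraries, and Meg3 and Miat had 0 counts in both. Of 14 structural small RNA genes 10 were at 1 TPM or more in both, while Rnu11, Rny1, Rny3 and Snord118 had 0 counts. The 13 mitochondrially encoded mRNAs were all above 100 TPM in both libraries. The subunit genes mt-Atp8 and mt-Co1 were at 12415 ± 14229 TPM and 10600 ± 6786 TPM, and mt-Co2 was lowest at 405 ± 388 TPM (SD, n = 2). The 35 ribosomal protein mRNAs, which are abundant in cytoplasm, were between 11.5 ± 1.24 TPM for Rpl37 and 80.6 ± 10.4 TPM for Rpl10 (SD, n = 2). The 15 highest genes of 200 nt or more also held the scaRNA gene Gm22009, mt-Nd6, mt-Nd1 and the mitochondria-derived pseudogenes Gm28661, Gm10925 and Gm10222, which share sequence with mitochondrial genes. Reads cannot be divided with certainty between these pseudogenes and mitochondrial genes, so the level and the rank of mt-Co2 are uncertain. Gm28661 held 36510 and 51856 expected counts in replicates 1 and 2, against 3538 and 2195 for mt-Co2.

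The fourth comparison was between the replicates. Among 11532 genes with a mean TPM of at least 1, 88.9% lay within 2-fold of the median ratio (95% Wilson interval 88.3 to 89.5%). Across these genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.915 and Spearman's rho 0.901. Over the 9158 nuclear protein-coding genes among them r was 0.965. The biological coefficient of variation was 0.231 over 12774 genes (edgeR common dispersion). The chi-square statistic per degree of freedom was 90.1 over 15667 genes, as a check that the tables are not copies of 1 library.

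Relative to the median of all genes, structural small RNAs stood 1.83 (log2) higher in replicate 2 than in replicate 1 and mitochondrially encoded mRNAs had a value of -1.17, at percentiles 100 and 0 of matched random lists. Of the 11 structural small RNA entries, in which Rmrp counts under both its identifiers, 10 stood higher, and Vaultrc5, on 2 and 5 counts, did not. Rn7s1 was at 20343 TPM in replicate 1 and 72626 TPM in replicate 2, and Rpph1 at 33904 and 74515 TPM. In the opposite direction, mt-Nd1 was at 6519 and 1525 TPM and mt-Co2 at 679 and 130 TPM, with mt-Co3 at 838 and 1073 TPM and mt-Nd4l at 1658 and 1790 TPM as the exceptions among 13 genes. Reads of mitochondrial genes cannot be divided with certainty from those of mitochondria-derived pseudogenes. Of these, Gm10222 was at 8020 and 860 TPM and Gm28661 at 7054 and 3095 TPM. Whether mt-Co3 and mt-Nd4l truly were exceptions, and the size of the mt-Co2 ratio, are therefore uncertain. Ribosomal protein mRNAs stood 0.49 higher in replicate 2 (percentile 100), macrophage identity genes 0.45 higher (percentile 99.8), secondary response genes 0.51 higher (percentile 99.5, but 0.39 and no longer outside the random range with TMM-scaled counts) and immediate early genes 0.29 higher (percentile 99.1). The lists of cytokines (0.03), interferon response (0.00), NF-kB feedback (0.25, but 0.42 and outside the range in the other quantification), negative regulators (0.17), TLR4 pathway (0.08), housekeeping (0.12), heat shock and stress (0.31), cell cycle (-0.08), nuclear noncoding RNA (-0.01) and other cell types (0.50) lay inside the range of random lists. In the other quantification other cell types turned to -0.34. Cytokines, interferon response and housekeeping stood there at 0.26, 0.26 and 0.35, still inside the range.

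**Figure D3:**
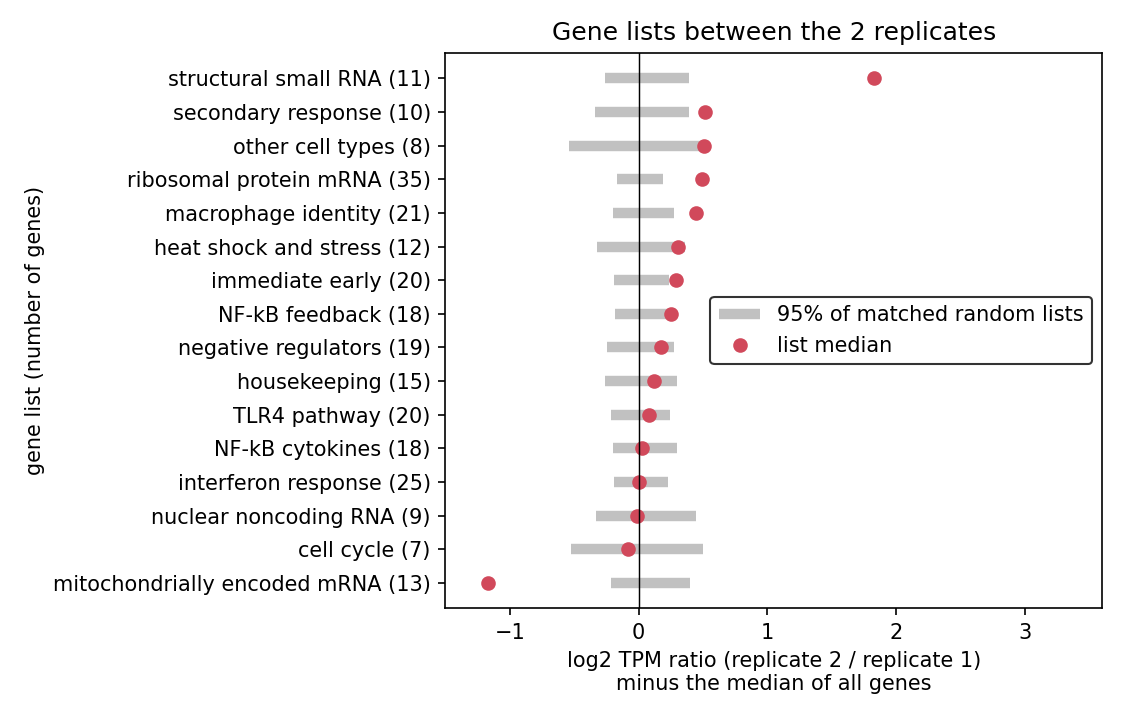
Points give the median log2 TPM ratio of each list, replicate 2 over replicate 1, relative to the median of all genes, and grey bars span 95% of random lists matched on mean TPM. Structural small RNAs lie at 1.83 and mitochondrially encoded mRNAs at -1.17, with ribosomal protein, macrophage identity, secondary response and immediate early genes also outside their bars.

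Single genes with the largest ratios were mostly short or hard to assign. Those higher in replicate 2 were the snoRNA genes Gm26447, Snord22 and Rnu3a, all listed at 0 TPM in replicate 1, the ribosomal RNA gene CT010467.1 at 75.4 and 892 TPM, the Rmrp-overlapping long noncoding gene at 3567 and 35590 TPM, and B430305J03Rik at 0 and 1556 counts. The 0 TPM did not always mean absence of counts. Expected counts in replicates 1 and 2 were 36.0 and 1129 for Gm26447, 1.96 and 663 for Snord22 and 0 and 158 for Rnu3a. B430305J03Rik had no count above 1 in either library of the other quantification. Those lower in replicate 2 were Gm37376, with 8791 and 0 counts, the small nuclear RNA copy Gm24497, Zfp993 at 73.3 and 4.24 TPM, mt-Atp8 at 22476 and 2353 TPM, and the pseudogenes Gm10222 and Gm28439. Gm37376 (chromosome 19, 5801941 to 5802393, plus strand) lies inside the span of Malat1 on the minus strand. Its reads cannot be told apart from Malat1 reads with certainty. The other quantification gave Gm37376 48872 and 31022 estimated counts, and Gm10222 0 in both. There the snoRNA genes had 132 and 1330.3 estimated counts for Gm26447, 16.2 and 794 for Snord22 and 119 and 827 for Rnu3a.

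The fifth comparison looked at isoforms. Of the transcript TPM of protein-coding genes, 72.4 ± 2.17% lay in protein-coding isoforms and 19.8 ± 1.61% in retained intron isoforms (SD, n = 2). These shares can include incompletely spliced RNA assigned to retained intron isoforms, and so need not be the use of finished isoforms. The noncoding isoform share had a median of 34.6% over 35 immediate early, cytokine and feedback genes and 14.2% over 26 macrophage identity and housekeeping genes. The difference of 20.4 percentage points, 20.0 in replicate 1 and 23.6 in replicate 2, had p = 0.024 (two-sided permutation test over genes, 1 test). The median over all 7676 such genes was 32.2%, and set against all other genes, a reference chosen after seeing the data, the response genes differed by 2.48 points (permutation test, p = 0.7). Within the lists, the median was 43.0% for feedback genes, 42.8% for interferon genes, 31.2% for cytokines, 14.6% for immediate early genes, 22.4% for housekeeping genes and 4.52% for macrophage identity genes. Oasl2 had the highest share among list genes, 92.8 ± 1.21%, followed by Rps23 at 89.9 ± 7.82%, Rpl5 at 88.3 ± 6.22% and Ppia at 85.5 ± 1.75% (SD, n = 2). The feedback genes Cd83, Nfkb1 and Tnip3 had 84.2 ± 1.04%, 83.9 ± 0.10% and 83.5 ± 6.43%, with 84.2%, 80.0% and 83.5% in retained intron isoforms, and Mx1 had 80.4 ± 10.1% (SD, n = 2). The macrophage genes Csf1r and Ctsd, chosen after their values were seen, had 0.80 ± 0.0268% and 0.714 ± 0.476% (SD, n = 2), and the highest of the 14 macrophage identity genes, Aif1 and Spi1, had 30.2 ± 23.5% and 25.8 ± 1.21% (SD, n = 2).

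**Figure D4:**
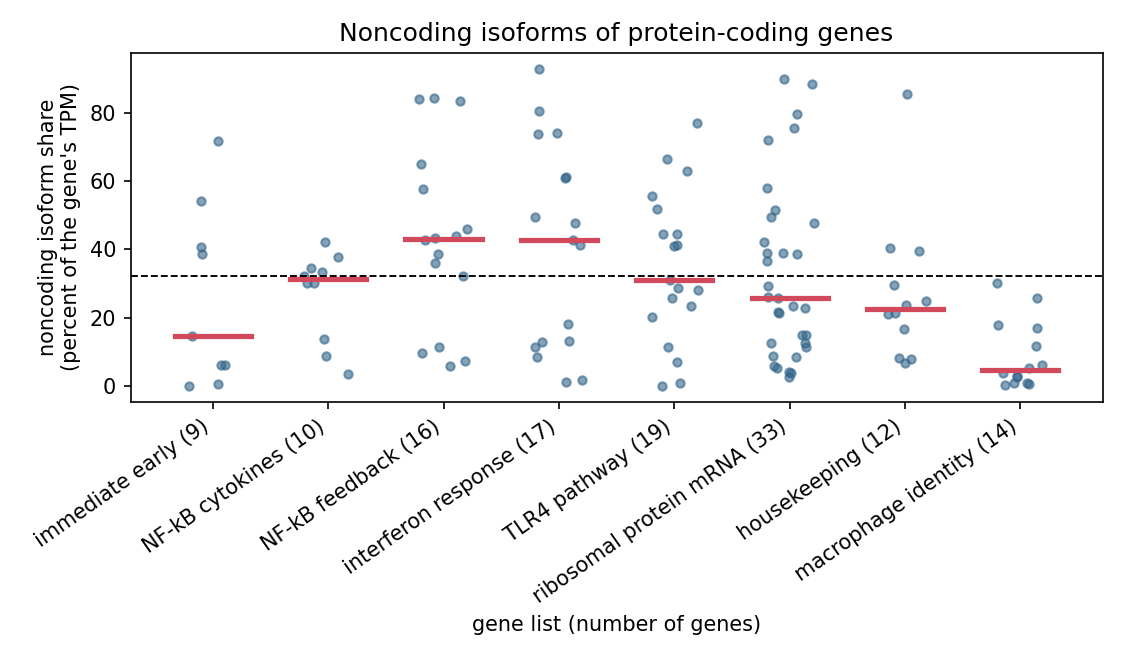
Each point is a gene, at the percent of its transcript TPM in isoforms not annotated as protein-coding, averaged over the 2 libraries, with list medians as red bars. The dashed line is the median of all such genes, 32.2%, and macrophage identity genes have the lowest median of the lists shown, 4.52%.

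The last comparison set the quantifications of the same library side by side. Across 11534 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) was 0.896 in replicate 1 and 0.942 in replicate 2, and Spearman's rho 0.875 and 0.922, across genes that are not independent replicates. The median gene was lower in the kallisto-layout table by a log2 difference of -0.25 in replicate 1 and -1.12 in replicate 2. In that table microRNA genes held 18.9% and 73.6% of TPM on 0.572% and 5.43% of estimated counts, against 0.00397% and 0.0129% of TPM in the other. After both were rescaled over nuclear protein-coding genes, the response genes that differed most were Nr4a2 by 1.99 ± 0.45, Bcl3 by 1.15 ± 0.50, Il27 by 1.08 ± 0.50, Nos2 by 1.06 ± 0.58 and Ccl9 by 1.05 ± 0.14 on the log2 scale (SD, n = 2), all higher in the kallisto-layout table. Il33 came next, but with 0 counts in the other table in both libraries, so no difference is given for it.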

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

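The tests of Malat1 and of cytoplasmic RNA in this part were chosen after the values had been seen, and those of transcript length before. Rows outside the gene annotation held a signal, the genome of the bacteriophage phiX174. It took 52407 expected counts, or 0.504% of the total (95% Wilson interval 0.4999 to 0.508%), in replicate 1 and 19842 counts, or 0.0967% (0.0954 to 0.0981%), in replicate 2, far above the 3 counts taken as the limit for 0. The 96 ERCC spike-in rows had 0 counts in both libraries. PhiX174 DNA is a common control in sequencing runs, and no explanation was tested for the difference between the libraries.

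The pattern of most interest between the replicates was that structural small RNAs stood higher and mitochondrially encoded mRNAs lower in replicate 2. Short transcript length was tested as the whole cause of the small RNA part. The 139 nuclear protein-coding genes of 200 to 600 nt stood 0.34 (95% bootstrap interval 0.21 to 0.47) above all genes on the log2 scale, against 1.83 for the structural RNAs. This argues against length only as an equal effect over 200 to 600 nt. The structural RNAs had a median length of 300 nt, below the 511 nt of those genes, so a steeper effect at shorter lengths stays open. For ribosomal protein mRNAs length stays open, since their shift was at percentile 97.7 of random lists matched on length, whose range was 0.02 to 0.49, too near its edge to decide. More cytoplasmic RNA of every kind in replicate 1, as a cause of the mitochondrial part, would put ribosomal protein mRNAs lower in replicate 2. They stood 0.49 higher, beyond the range of -0.17 to 0.19 of random lists matched on mean TPM. Among lists matched on length they were not lower either. Since length stays open for their shift, these values cannot decide on cytoplasmic RNA. Cytoplasmic RNA, RNA from mitochondria alone and the 500 ng and 1 µg inputs stay open, each with a single library. No biological explanation was tested because the design has 1 group.

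Malat1 was 3.23-fold higher in TPM in replicate 1, a log2 ratio of -1.69, whereas its share of counts had a log2 ratio of -0.29. Relative to the common shift of all genes the TPM ratio was -1.001, and the other quantification, in which the common shift of all genes was -2.26, gave 23137 and 2654 TPM. A candidate explanation for part of this is that similar shares of reads were given to isoforms of different length, as its mean transcript length was 3352 nt in replicate 1 and 5610 nt in replicate 2, a log2 ratio of -0.74 (replicate 1 over replicate 2). The isoform Malat1-203 held 4.71% of the gene's counts and 18160 TPM in replicate 1 and 0.280% and 513 TPM in replicate 2. Malat1-201, which held 95.3% and 98.3% of the gene's counts, was at 14373 TPM in replicate 1 and 7910 TPM in replicate 2. As TPM divides counts by length, the difference in length enters the TPM ratio by construction. Whether the isoforms truly differed between the libraries stays open, because the share of counts that prompted the explanation cannot test it.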

How the results depend on the processing

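Of 72 alternatives to the 8 list comparisons (9 each), 69 kept the direction and the side of the threshold. With only genes of mean TPM of at least 1, the difference to the secondary list was 1.93 for immediate early genes and 1.34 for interferon genes, with adjusted p = 0.05 and 0.068, no longer past the threshold, because that filter removes 8 of the 18 secondary genes by its construction. Immediate early minus interferon genes ranged from 0.46 to 0.91 when a replicate was left out, and passed the threshold without replicate 1. The cause was not tested here or for the values below. The biological coefficient of variation was 0.268 with at least 1 count in total, 0.204 with at least 100 counts in both libraries, 0.202 for protein-coding genes of 200 nt or more and 0.266 from DESeq2 dispersions. The share of genes within 2-fold was 90.5% with TMM-scaled counts, 94.0% at a mean TPM of at least 10, 77.0% at 0.1, 84.1% in the other quantification and 93.2% for protein-coding genes. By share of counts, long noncoding genes held 16.4%, nuclear protein-coding genes 69.6% and small RNA 8.05%. Without genes under 200 nt, long noncoding genes held 7.72%. The other quantification gave 4.59 ± 4.08% for long noncoding genes, 14.2 ± 12.6% for protein-coding genes and 15.1 ± 11.9% for pseudogenes and other genes (SD, n = 2), so its libraries differed widely. It gave 2.94% for the mitochondrial genome. In the main quantification the mitochondrial share was 2.34% without replicate 1 and 7.75% without replicate 2. The response genes' noncoding isoform share kept its call under the 6 alternatives chosen before the values were seen. Against all other genes, a reference chosen after seeing the data, the difference was 2.48 points (permutation test, p = 0.7). The correlation of the quantifications was 0.828 without a filter and 0.952 for protein-coding genes of 200 nt or more. List shifts between the replicates with TMM-scaled counts were 0.39 for secondary response (then at the edge of the random range and no longer outside it) and -0.21 for nuclear noncoding RNA. In the other quantification they were 0.26 for cytokines, 0.42 for feedback (then outside the random range), 0.26 for interferon, 0.35 for housekeeping and -0.34 for other cell types. Counts of list members at 1 TPM or more, an alternative added after seeing the data, moved beyond 1.5 times for other cell types, with 15 on rescaled TPM and 2 in the other quantification. The level of a single gene kept within its SD in 195 of 1071 cases over 3 other scales, chosen after seeing the data, so gene levels are comparable within a scale only. With 2 libraries, replicate 1 at 10395300 counts, genes of a few counts such as Fpr1 and Il12a have no usable ratio. No paired analysis was possible because there is 1 group.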

Other observations

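The long noncoding genes of this paragraph were chosen from the 30 with the highest shares of counts, after their values were seen. Lncpint was at 300.4 ± 116 TPM, Mir22hg, the host of miR-22, at 229 ± 18.7 TPM and Dleu2, the host of miR-15a and miR-16-1, at 116 ± 34.6 TPM (SD, n = 2). Gm14636 held 0.341% of expected counts in replicate 1 and 0.242% in replicate 2, more than Mir155hg at 0.0405% and 0.0407%. Gm26917 and Gm42418, long noncoding genes on which ribosomal RNA reads are known to collect, held 0.212% and 0.103% of counts in replicate 1 and 0.791% and 0.281% in replicate 2.

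The nuclear protein-coding genes of this paragraph were also chosen after their values were seen, some for a high TPM and the last 3 for their difference between the replicates. Psap, which encodes the lysosomal precursor prosaposin, was at 3539 ± 375 TPM, Gpnmb at 2482 ± 571 TPM, H2-K1 at 1664 ± 686 TPM and Tnfaip2 at 1526 ± 490 TPM (SD, n = 2). The paralogs Lilr4b and Lilrb4a were at 2605 ± 1316 TPM and 1935 ± 777 TPM (SD, n = 2), and reads of such paralogs cannot be divided between them with certainty. The apolipoprotein gene Apoe was at 502 TPM in replicate 1 and 894 TPM in replicate 2. Matn4 had 29 and 631 counts, and 135 and 1005 estimated counts in the other quantification. The lymphotoxin gene Ltb had 5 and 159 counts, and 23 and 221 in the other quantification.

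Macrophage identity genes had a low noncoding isoform share, a median of 4.52% over 14 genes. Both tests here were chosen before their results were seen. The list was followed up because its median was low, so a low percentile was partly fixed by that choice. Number of isoforms and level were not matched together. Fewer annotated noncoding isoforms were argued against as the whole cause, since the median was at percentile 0.47 of 10000 random lists matched on the number of such isoforms, below their range of 6.97 to 34.0%. A high level was argued against as the whole cause as well, since the median was at percentile 0 of lists matched on mean TPM, whose range was 20.8 to 56.3%. No biological explanation was tested, and ribosomal protein mRNAs had a median of 25.7%.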
